A study of Mus musculus with 16 samples.

How the data were processed

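RNA was measured in CD8 T cells of 7-week-old female C57BL/6N mice. Cells positive for CD8 and Thy1.2 were sorted by flow cytometry into a CD44-low (naive) and a CD44-high (memory phenotype) fraction. Each fraction was cultured for 4 h either in medium alone (resting) or with PMA at 10 ng/mL and ionomycin at 500 ng/mL (stimulated). PMA activates protein kinase C and ionomycin raises intracellular calcium, so that the pair bypasses the T cell receptor. About 200 ng of total RNA was amplified with an oligo-dT T7 primer and labelled with Cy3, per the labels' protocols, which ties the signal to sequence near the 3' end of a transcript. The 16 arrays fall into 4 groups of 4, namely naive resting, memory resting, naive stimulated and memory stimulated. The series' design text says that the whole sort and culture was carried out on 4 separate occasions, so the spread between replicates includes the sort, the culture, the labelling and the array.

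Each sample was hybridised alone to a whole mouse genome array with 4 arrays on a slide and probes of 60 bases. Per the file headers, the authors scanned the slides in 1 colour and extracted them with Agilent Feature Extraction 9.5.3.1, which subtracted background, removed spatial and multiplicative trends and put a positive surrogate in place of signals near background. The deposited intensity of each spot (the processed Cy3 signal) is therefore on a linear scale, corrected within its array and not normalized between arrays. The files also hold the mean spot intensity and the median local background intensity, per the file headers, and flags for spots well above background, saturated or outlying. A deposited table of 33797 spots holds the authors' own processed intensities. Its processing is not given in the sources used here, and its values were found to be linear, with a lowest value of 30. The median of 149.0 and the quartiles of 44.0 and 1113.0 to 1114.0 were the same or nearly so on every array, so the table looks quantile normalized. The values correlate with the log2 processed signal of the same array at 0.9918 or more. The slope on log2 processed signal was 0.853 to 0.932, so the table's fold changes are compressed. It served as an alternative only.

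The processed signal was converted to log2, and the 75th percentile of each array over the 41174 non-control probes was subtracted, so that 0 stands for that percentile and each unit for a doubling. Control spots and spots marked as outliers by the extraction software (59 to 116 of 43379 per array) were left out, 1 saturated spot was kept, and replicate spots of a probe were averaged. The 75th percentile lay between 504.3 and 678.0 intensity units, and 59.3% to 66.5% of spots were well above background. The number of arrays limits the precision. A probe was tested where it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 27349 probes. Symbols came from the reference table through the probe's RefSeq accession, symbol or an older synonym for 32737 probes, and 8437 kept the name in the files. A gene with several tested probes (6043 genes) was represented by the probe with the highest mean over all 16 arrays, giving 18401 genes. Probes of one gene did not always move together. Counting each probe on its own, 384 genes had probes called in opposite directions in the naive response and 365 in the memory response, and between 22 and 49 did so in the other comparisons. Positions are those of the probes on mouse build mm7 (NCBI35), as the files give them, and their exon, intron or UTR annotation was not used here.

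One linear model with a mean per group was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with version 1.17.8 of the data.table package and Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for reading the files and drawing. Sharing 1 estimate of the spread over the groups keeps the residual degrees of freedom of all arrays. The 5 contrasts were the naive response (stimulated minus resting), the memory response, the resting difference (memory minus naive), the stimulated difference (memory minus naive) and the interaction (memory response minus naive response). Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and the threshold was an adjusted p of 0.05. Every adjusted p for a gene comes from this limma fit. Log2 changes are given with standard errors (SE) from the fit and group levels as mean ± SD with n = 4. Where a probe was not well above background on any array of a group, the change is only a bound. It is written as "at least N-fold", the mean of the bright group against the mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. No fold is given where this came out under 1.

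The 15 gene lists and 8 lists of cell type markers were fixed before the data were examined, as were the tests, the other settings to be tried and the rule for naming genes. List tests used limma's camera with a preset correlation of 0.01 between genes and again with the correlation estimated from the data, adjusted over the lists within a comparison. The gene lists were immediate early and activation transcription factors, cytokines and chemokines, cytotoxic granule genes, memory and effector CD8 T cell genes, naive and quiescence genes, NF-kappaB pathway genes, activation-induced receptors, ribosome biogenesis, cell cycle, interferon-stimulated, glycolysis, sterol synthesis and uptake, chromatin-modifying enzymes, apoptosis regulators, and heat shock and stress genes. The marker lists covered T cells, B cells, monocytes with macrophages and neutrophils, dendritic cells with MHC class II, NK or NKT cells, CD4 or regulatory T cells, gamma-delta T cells, and erythrocytes or platelets. Genes named for a comparison were the 10 with the largest rise and the 10 with the largest fall past the threshold that had a gene symbol and moved the same way in all 4 same-numbered differences, members of the fixed lists, the markers, and Cd44, Cd8a and Thy1. Not every gene that met this rule is named.

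Each slide held the 4 arrays of 1 group, and all slides were scanned on 1 day at different times. Slide, scan time and group therefore cannot be told apart, and a fit with the slide or the scan date as a block could not be run. Every difference between groups below is also a difference between slides.

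In simulated data 200 of 18401 genes were changed, a far smaller share than called here, so recovery in the real fit may differ. At 1.5-, 2- and 4-fold the model recovered 4.48%, 35.8% and 78.8% of the changed genes for the interaction. In other comparisons the shares were 20.9% to 37.3%, 59.7% to 67.2% and 90.9% to 97.0%. Shares of 66 or 67 genes do not rank comparisons. Between 1 and 8 unchanged genes were called.

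The other settings chosen at that stage were normexp background correction (offset 50) of the mean and background intensities with 75th percentile or quantile scaling, quantile scaling of the processed signal, scaling on the median of probes detected on every array, the authors' table, other filters on dim probes, other rules for several probes, fits on only the groups compared, with the replicate number as a fixed or random block, with a trend and robust variances, stricter thresholds, the estimated correlation for lists, and leaving out each array in turn. Normexp was fitted to the means of non-control, unflagged probes rather than to all spots. The fit failed on 3 arrays, and the 75th percentile and the quantile scaling both rest on it. On naive stimulated replicate 1 and memory stimulated replicates 1 and 2, 6, 13 and 10 probes had a local background far above their signal, down to a net signal of -9300, -64700 and -52000, and pulled the fitted background mean to -287, -887 and -665 against -5.67 to -11.4 on the other arrays. Its values are kept as run, and a repaired version without probes whose local background exceeded 2 times the array's median was added after this was seen. Also added after the data were seen were fits on genes with a mean level of at least 0, with a correction for probe GC content, without probes of telomeric repeat or of sensory receptor, keratin-associated and defensin genes, without naive resting replicates 1 and 4, and with 1 factor estimated from sensory receptor probes. That factor was -0.31 to -0.01 on naive resting and 0.07 to 0.32 on memory resting arrays. It was 0.19 to 0.35 on naive stimulated and -0.35 to -0.22 on memory stimulated arrays. The factor thus largely follows the groups, in the shape of the interaction. Fitting it takes up part of the group differences and widens their errors. A call lost under it therefore does not show that a difference is absent. For a gene with several probes, the fit of each probe on its own was read at the probe with the highest adjusted p, a choice also made after the data were seen.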

Results

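Transcript levels were measured in CD8 T cells, the lymphocytes that kill infected cells, from C57BL/6N mice. Cells with little surface CD44 were taken as naive and cells with much of it as memory phenotype. Both were kept for 4 h in medium alone or with PMA and ionomycin, a pair of drugs that triggers T cell activation from inside the cell. Each of the 4 groups (naive resting, memory resting, naive stimulated, memory stimulated) had 4 arrays. Levels are log2 signal relative to the array's 75th percentile (504.3 to 678.0 intensity units), so that 0 is that percentile. Spots well above background were 63.9% to 66.5% on memory resting and 59.3% to 61.4% on memory stimulated arrays. Pearson's r across genes between replicates of a group was 0.9784 to 0.9953, and genes are not independent replicates. Of 18401 genes tested, 6761 rose and 5895 fell in naive cells after stimulation, and 5533 rose and 7505 fell in memory cells. Memory cells differed from naive cells at rest in 3923 genes and after stimulation in 4433 genes. Each group was hybridised on its own slide, so group and slide cannot be told apart in any of these comparisons.

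**Figure D1:**
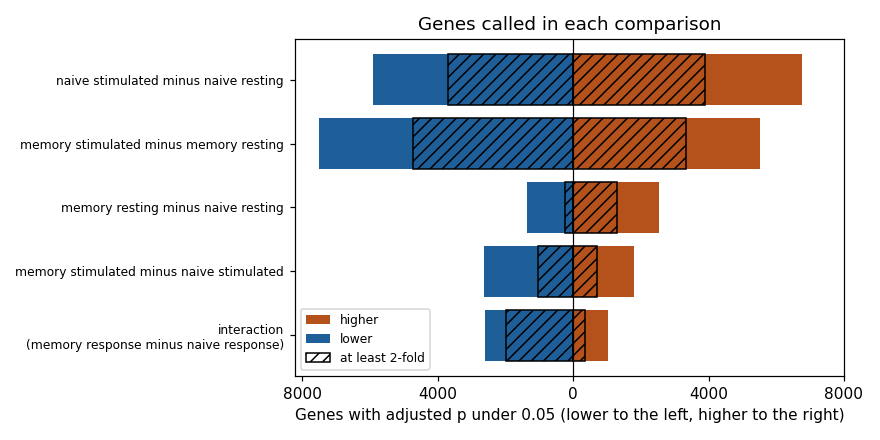
Genes with an adjusted p below 0.05 (limma) in each of the 5 comparisons, with lower genes as bars to the left and higher genes to the right of 0; the hatched part is the genes that changed at least 2-fold. The naive response had 6761 higher and 5895 lower genes, and the interaction 1033 higher and 2600 lower.

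The genes of the sort were read before the comparisons. Cd44, the adhesion receptor used for the sort (mm7 chromosome 2, 102663537 to 102663596), was at -0.58 ± 0.13 (SD, n = 4) in naive resting cells and 3.47 ± 0.10 in memory resting cells, a difference of 4.05 ± 0.19 (SE; adjusted p = 1.52e-09). Since the cells were chosen by this protein, this is a check of the labels and not a finding. Of the 3 Cd44 probes tested, the second differed at rest by 4.17, and the third, at levels of -5.85 to -4.05 and so near background, by 0.09 (adjusted p = 0.86). Stimulation raised Cd44 by 3.80 ± 0.19 in naive cells and by 2.33 ± 0.19 in memory cells. Cd8a, which encodes a chain of the CD8 co-receptor, did not pass the test between memory and naive cells at rest (0.19 ± 0.21, adjusted p = 0.565) and fell after stimulation by 1.59 ± 0.21 in naive and by 1.38 ± 0.21 in memory cells. Thy1, a T cell surface protein, differed by 0.17 ± 0.22 at rest (adjusted p = 0.631). It rose in stimulated memory cells by 0.81 ± 0.22 (adjusted p = 0.0042), a call that ended with quantile scaling of the processed signal (0.17, adjusted p = 0.45).

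**Figure D2:**
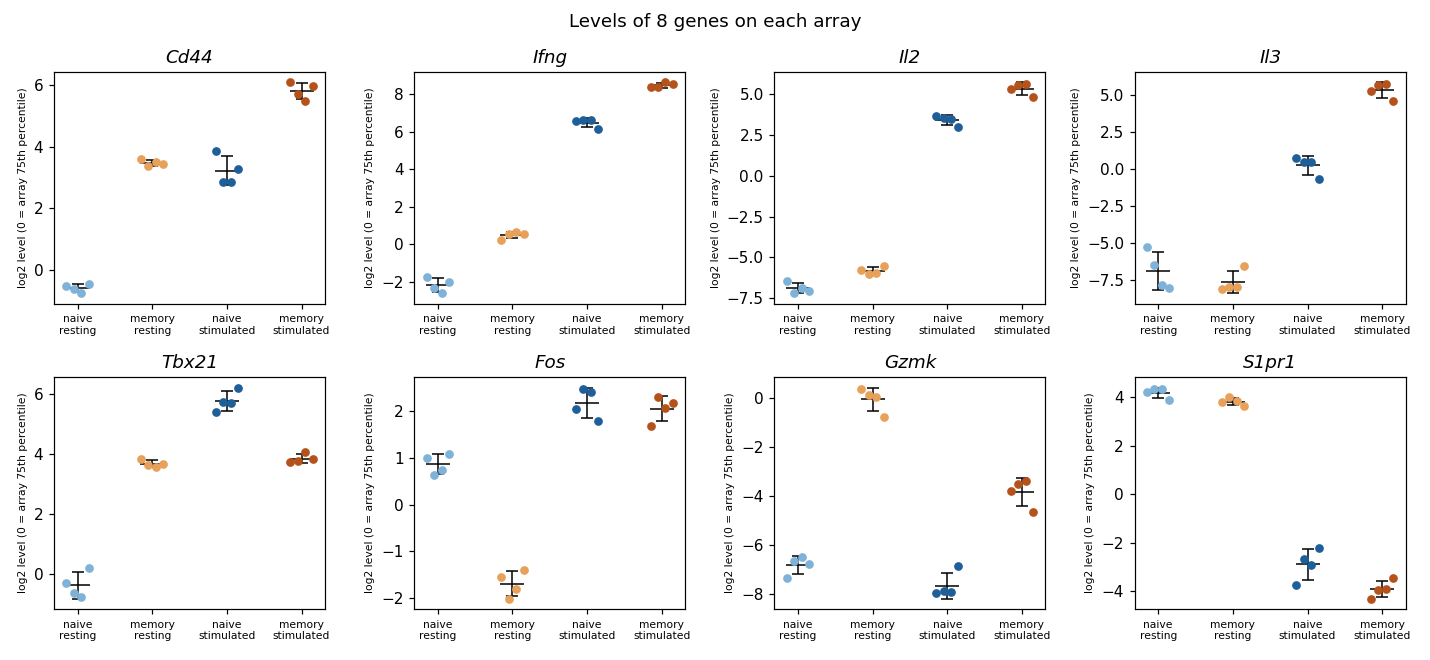
Level of 8 genes on each of the 16 arrays (points; log2 signal relative to the array's 75th percentile), with the mean and SD of each group of 4. Cd44 was at -0.58 in naive and 3.47 in memory cells at rest, Ifng and Il2 rose in both cell types, and Tbx21 rose in naive cells alone (6.12 against 0.17, interaction adjusted p = 2.06e-09).

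The first comparison asks how naive cells answer 4 h of stimulation. Stimulated naive cells gained transcripts of Il2, Xcl1 and Ifng and lost those of S1pr1 and Slc6a19. Il2, the T cell growth factor (chromosome 3, 36936354 to 36936512), was not well above background on any naive resting array and at 3.43 ± 0.29 after stimulation, at least 550-fold higher (adjusted p = 1.17e-14). The chemokine Xcl1 (chromosome 1, 164899708 to 164899767) rose from -2.69 ± 0.26 to 6.32 ± 0.28, and interferon gamma (Ifng; chromosome 10, 117841087 to 117841146) rose by 8.63 ± 0.17 on the log2 scale, with adjusted p of 7.05e-15 and 1.17e-14. S1pr1, the receptor that lets T cells leave lymphoid tissue (chromosome 3, 115486015 to 115486074), fell by 7.08 ± 0.26 (adjusted p = 4.66e-12), and Slc6a19, a neutral amino acid transporter, was at least 112-fold lower (adjusted p = 1e-14).

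The other genes with the largest rises in naive cells were Sema7a (8.42 ± 0.11), the chemokines Ccl4 (8.34 ± 0.16) and Ccl3 (8.25 ± 0.14), Tnfsf14 (8.02 ± 0.18). Next were the aminotransferase Bcat1 (7.32 ± 0.20), Zbtb32 (at least 165-fold) and the cytokine Il3. Il3 rose by 7.14 ± 0.55, with 1 of 4 naive resting arrays above background. Their adjusted p ran up to 1.36e-08. Other large falls were in Rflnb (-7.28 ± 0.32, with 3 of 4 stimulated arrays above background), the cannabinoid receptor Cnr2 (-7.08 ± 0.19, 2 of 4), Fam78a (-6.48 ± 0.14) and the interleukin 18 receptor gene Il18r1 (-6.09 ± 0.25). Art4, Siae and Gprc5b were at least 61.7-, 49.4- and 48.1-fold lower. The highest adjusted p of these falls was 5.99e-11.

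All 30 measured ribosome biogenesis genes rose in naive cells, with a median of 2.83 (camera adjusted p = 1.85e-15; adjusted p = 0.14 with an estimated correlation). Examples were Polr1b, a subunit of RNA polymerase I (3.89 ± 0.13), and Mrto4 (3.85 ± 0.11). Of 21 immediate early and activation transcription factors 19 rose, none fell and 2 did not pass, with a median of 2.53 (camera adjusted p = 1.03e-07; adjusted p = 0.126 with an estimated correlation). Among them were Fosl1 (6.34 ± 0.31), Irf8 (6.17 ± 0.19), Irf4 (5.73 ± 0.15) and Myc (4.68 ± 0.11). Of 30 cytokines and chemokines 22 rose, 2 fell and 6 did not pass (camera adjusted p = 5.95e-06; adjusted p = 0.14 with an estimated correlation). Csf2, which encodes GM-CSF, was at least 16.8-fold higher, and lymphotoxin beta (Ltb) fell by 2.36 ± 0.15. Of 21 activation-induced receptors 17 rose and 3 fell (camera adjusted p = 5.08e-06; adjusted p = 0.159 with an estimated correlation). They include the interleukin 2 receptor chain Il2ra (5.79 ± 0.32), Cd160 (5.64 ± 0.26, with 2 of 4 resting arrays above background) and the inhibitory receptor Lag3 (at least 23.5-fold).

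Of 29 naive and quiescence genes 18 fell, 2 rose and 9 did not pass, with a median of -1.73 (camera adjusted p = 6.42e-06; adjusted p = 0.14 with an estimated correlation). Beside S1pr1, the interleukin 7 receptor gene Il7r fell by 5.70 ± 0.24, Tsc22d3 by 5.29 ± 0.17 and Pik3ip1, an inhibitor of PI3 kinase, by 5.01 ± 0.17. Of 27 interferon-stimulated genes 18 fell and 1 rose (camera adjusted p = 0.00323; adjusted p = 0.631 with an estimated correlation). Examples were Ifit2 (-3.96 ± 0.26) and Oasl2 (-3.39 ± 0.45). Of 19 genes of sterol synthesis and uptake 13 rose, for example Idi1 (4.55 ± 0.15) and Sqle (3.76 ± 0.12), and 5 fell, for example Mvk (-1.93 ± 0.18). The sterol list passed narrowly (camera adjusted p = 0.0469; adjusted p = 0.514 with an estimated correlation). It did not pass without naive resting replicate 1 (0.0741), memory resting replicate 1 (0.0533) or memory stimulated replicate 4 (0.0503). The remaining lists did not pass. They were NF-kappaB pathway genes (12 rose and 3 fell of 20, adjusted p = 0.0511), heat shock and stress genes (9 and 3 of 16, 0.0673) and cytotoxic granule genes (9 and 4 of 16, 0.259). The others were glycolysis (11 and 3 of 22, 0.259), memory and effector genes (15 and 9 of 31, 0.323), cell cycle (8 and 12 of 33, 0.532), apoptosis regulators (8 and 9 of 22, 0.684) and chromatin-modifying enzymes (16 and 20 of 45, 0.836). The NF-kappaB list passed without any 1 of naive resting replicates 2 and 4, naive stimulated replicates 2, 3 and 4 or memory stimulated replicate 1 (0.0424 to 0.0481), and the heat shock list without naive stimulated replicate 1 (0.0347). Single members of these lists changed strongly. Tbx21, which encodes the transcription factor T-bet, rose by 6.12 ± 0.20, Zeb2 by 6.21 ± 0.20, granzyme B (Gzmb) by 5.95 ± 0.59, the NF-kappaB subunit Rel by 5.30 ± 0.26 and hexokinase 2 (Hk2) by 4.63 ± 0.28. Gzmc was at least 9.3-fold higher, and Bcl3 (-3.90 ± 0.18) and Unc13d (-3.07 ± 0.18) fell. The counts adjusted over the list alone were the same, except for 16 memory and effector genes and 17 chromatin-modifying enzymes that rose. For chromatin-modifying enzymes the median was -0.01 and the mean 0.13, and for apoptosis regulators 0.18 and -0.23, while both tests pointed down.

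Markers of other cell types moved in the same comparison. Of 14 monocyte, macrophage or neutrophil genes 9 fell and 1 rose (camera adjusted p = 0.0689). Of the neutrophil genes S100a9 was at -3.06 ± 0.42, S100a8 at -3.25 ± 0.52 and Ngp at -4.02 ± 0.66, the last above background on 2 of 4 stimulated arrays. Of 9 dendritic cell and MHC class II genes 5 rose (0.319). Counts in the T cell list were 3 up and 7 down of 11 (0.319), in B cells 0 and 1 of 7 (0.531). In NK or NKT cells they were 3 and 3 of 11 (0.843; 3 and 2 adjusted over the list alone), in CD4 or regulatory T cells 1 and 2 of 5 (0.843) and in erythrocytes or platelets 1 and 1 of 4 (0.843). Elsewhere in these marker lists the counts adjusted over the list alone were the same.

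The second comparison asks the same of memory phenotype cells. These cells gained the cytokines Il3, Il2 and Csf2 and 2 genes with little signal in naive cells, the chemokine Ccl1 and interleukin 17A (Il17a). Il3 (chromosome 11, 54222252 to 54222311) was not well above background at rest and at 5.30 ± 0.54 after stimulation, at least 2190-fold higher (adjusted p = 2.04e-11). Il2 rose by 11.19 ± 0.21, with 2 of 4 resting arrays above background. Csf2 was at least 511-fold, Ccl1 at least 83.8-fold and Il17a at least 58.8-fold higher, with adjusted p of 2.5e-11, 1.74e-10 and 1.98e-08. S1pr1 fell by 7.73 ± 0.26 (adjusted p = 1.99e-12).

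The other largest rises in memory cells were in Sema7a (8.02 ± 0.11), Ifng (7.95 ± 0.17), Fosl1 (7.73 ± 0.31, with 2 of 4 resting arrays above background), Xcl1 (7.67 ± 0.16) and Spry1, a regulator of receptor signalling (7.51 ± 0.16). Other large falls were in Cnr2 (-6.65 ± 0.19), Pik3ip1 (-5.92 ± 0.17), the potassium channel gene Kcnj8 (-5.83 ± 0.35), Rnf32 (-5.53 ± 0.30) and Tsc22d3 (-5.49 ± 0.17), of which Cnr2 and Rnf32 were above background on 2 of 4 stimulated arrays. Rflnb was at least 140-fold, Art4 at least 71.5-fold and Slc6a19 at least 16.7-fold lower. Adjusted p in these genes was 7.86e-10 or less.

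All 30 ribosome biogenesis genes rose in memory cells too, with a median of 3.09 (camera adjusted p = 6.02e-19; adjusted p = 0.105 with an estimated correlation). Of 21 immediate early and activation transcription factors 20 rose and none fell, with a median of 3.75 (camera adjusted p = 2.21e-11). This was the only list of the 2 responses that passed with an estimated correlation as well (adjusted p = 0.0333). Fos rose by 3.75 ± 0.19, Nr4a1 by 4.66 ± 0.13, Egr2 by 6.43 ± 0.18 and Myc by 5.97 ± 0.11. Of 30 cytokines and chemokines 25 rose and 2 fell (camera adjusted p = 7.12e-10; adjusted p = 0.0655 with an estimated correlation). Of 21 activation-induced receptors 17 rose and 2 fell (7.3e-08; adjusted p = 0.111 with an estimated correlation), with Il2ra at 6.05 ± 0.32. Of 29 naive and quiescence genes 20 fell and 5 rose (camera adjusted p = 0.000469; adjusted p = 0.218 with an estimated correlation), with Il7r at -5.36 ± 0.24. Of 27 interferon-stimulated genes 22 fell and none rose (camera adjusted p = 0.000372; adjusted p = 0.44 with an estimated correlation). Among them were Oasl2 (-4.07 ± 0.45), Oas2 (-4.04 ± 0.52, with 1 of 4 stimulated arrays above background) and Irf1 (-3.23 ± 0.20).

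Sterol genes (11 rose and 4 fell of 19, camera adjusted p = 0.0106; adjusted p = 0.312 with an estimated correlation), NF-kappaB genes (11 and 4 of 20, 0.0059; adjusted p = 0.312 with an estimated correlation) and heat shock and stress genes (10 and 3 of 16, 0.00578; adjusted p = 0.386 with an estimated correlation) also passed. With quantile scaling of the processed signal the NF-kappaB and heat shock lists did not (adjusted p = 0.13 and 0.103), nor did they with the authors' table (0.124 and 0.119). Lists that did not pass were cytotoxic granule genes (9 and 4 of 16, 0.0742), glycolysis (11 and 5 of 22, 0.0742), chromatin-modifying enzymes (20 and 17 of 45, 0.348). The others were memory and effector genes (10 and 11 of 31, 0.553), cell cycle (7 and 13 of 33, 0.801) and apoptosis regulators (9 and 8 of 22, 0.835, with a median of 0, a mean of -0.23 and a test pointing up). Glycolysis passed without memory resting replicate 1 (0.0423) or naive resting replicate 1 (0.049). With p adjusted over the list alone, 11 heat shock genes rose and 18 chromatin-modifying enzymes fell, and the other counts of these lists were the same. As in naive cells, neutrophil genes fell, with S100a9 at -3.43 ± 0.42 and Ngp at -4.25 ± 0.66. In all, 10 of 14 genes of the monocyte, macrophage or neutrophil list fell and 1 rose (0.0903). B cell markers showed 0 up and 5 down of 7 (0.252), CD4 or regulatory T cell markers 1 and 4 of 5 (0.47) and erythrocyte or platelet markers 0 and 3 of 4 (0.554). NK or NKT markers showed 1 and 5 of 11 (0.575), T cell markers 3 and 5 of 11 (0.824) and dendritic cell and MHC class II markers 1 and 2 of 9 (0.824). Among the markers adjusted over the list alone, 6 T cell markers fell and no dendritic cell or MHC class II marker passed.

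The 2 responses shared no array and were correlated. Of the genes that rose, 4651 rose in both against 2033 for independent lists, and of those that fell, 5000 fell in both against 2404. With 1 factor taken from sensory receptor probes (the receptor factor) 2303 genes rose and 2384 fell in both. The factor largely follows the groups, so here and below a call lost under it does not show that a difference is absent. Without the factor a further 799 genes rose in naive and fell in memory cells, and 72 did the reverse. The log2 changes correlated across the 18401 genes at a Pearson's r of 0.822 (Spearman's rho 0.766; r = 0.594 with the receptor factor), with a covariance of 1.819, and across the 7580 genes with a mean level of at least 0 at 0.934. Genes are not independent replicates. The median change over all genes was 0.11 in naive and -0.21 in memory cells, and with quantile scaling of the processed signal 0.01 and -0.12. The share of called genes that rose in memory cells, 42.4%, became 52.9% (6086 rose and 5408 fell) with normexp background correction repaired and the same scaling. It became 56.8% (4634 and 3521) with the receptor factor and 59.8% (3592 and 2417) among genes with a mean level of at least 0, and the share in naive cells, 53.4%, became 41% (3422 and 4930) with that factor. Under it Ngp (-3.43, adjusted p = 0.0745) and interferon-stimulated genes (median -1.295, 0.103) did not pass in naive cells. Nor did sterol genes in memory cells (0.841, 0.144), and the NF-kappaB list passed in naive cells (0.0319).

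The third comparison sets memory against naive cells at rest. Resting memory cells had far more transcript of several killer cell lectin-like receptor genes and of the granzyme Gzmk, and less of the chemokine receptor Ccr9. The Ly49 receptor gene Klra4 was not well above background in naive cells and at 1.26 ± 0.08 in memory cells, at least 119-fold higher (adjusted p = 4.74e-08). Gzmk, a granzyme (chromosome 13, 110327790 to 110327849), was at least 48.4-fold higher (adjusted p = 1.52e-09), and the gut-homing receptor Ccr9 (chromosome 9, 123499521 to 123499580) was lower by a log2 change of -3.76 ± 0.21 (adjusted p = 5.15e-09). In all, 2548 genes were higher and 1375 lower, of which 1299 and 235 changed at least 2-fold.

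Among the other largest differences, Klra23 was higher by 7.47 ± 0.31, Klra7 by 7.40 ± 0.37, Klra16 by 6.75 ± 0.28 (3 of 4 naive arrays above background), Klrc1 by 6.34 ± 0.24 and Cd163l1 by 5.72 ± 0.33. Klra6 was at least 46.3-fold, Dmrta1 at least 24.4-fold and Klre1 at least 17.4-fold higher. Genes of the Klra family are close in sequence, and signal shared between their probes was not tested. Lower in memory cells were the prohormone convertase gene Pcsk1 (-3.69 ± 0.24), Lrrc75b (-3.27 ± 0.21), Pdgfrb (-2.96 ± 0.66, 1 of 4 memory arrays above background), Tcf7l2 (-2.93 ± 0.28). So were Rgcc (-2.89 ± 0.26), Gprc5b (-2.87 ± 0.32), the urokinase receptor gene Plaur (-2.86 ± 0.24) and Zcchc12 (-2.74 ± 0.39, 1 of 4 memory arrays). P2rx5 was at least 1.88-fold lower. Adjusted p in these genes was 0.00468 or less. Pdgfrb (-2.62, adjusted p = 0.248) and P2rx5 (0.307) did not pass with the receptor factor. A second Tcf7l2 probe did not pass (-0.31, adjusted p = 0.582), and Pdgfrb in naive resting replicate 2 was at -1.20 against a mean of -4.10 on the other 3 arrays.

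Of 31 memory and effector CD8 T cell genes 28 were higher, 1 lower and 2 did not pass, with a median of 2.84 (camera adjusted p = 5.13e-27; adjusted p = 0.000151 with an estimated correlation). Cd44 is a member and was the sort marker. Other members were the chemokine receptor Cxcr3 (4.56 ± 0.23), Klrg1 (5.23 ± 0.52, 2 of 4 naive arrays above background), Tbx21 (4.05 ± 0.20), S100a6 (3.72 ± 0.17) and Klrk1 (at least 19.3-fold). The lower member was the integrin gene Itga4 (-1.05 ± 0.35, adjusted p = 0.0431), which did not pass without memory resting replicate 1 or 4, naive resting replicate 2 or 3, naive stimulated replicate 2, 3 or 4, or memory stimulated replicate 2 or 4 (0.0508 to 0.128), and was at 0.47 with the receptor factor (adjusted p = 0.604). Of 21 immediate early and activation transcription factors 15 were lower and 1 higher in memory cells (camera adjusted p = 2.15e-09; adjusted p = 0.033 with an estimated correlation). Fos (-2.56 ± 0.19), Nr4a1 (-1.99 ± 0.13), Egr2 (-1.80 ± 0.18) and Myc (-1.37 ± 0.11) were lower and Irf8 (2.58 ± 0.19) higher. These 2 lists passed with an estimated correlation.

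The other lists that passed did so only with the preset correlation. Of 30 cytokines and chemokines 12 were higher and 1 lower (camera adjusted p = 1.1e-05; adjusted p = 0.139 with an estimated correlation), with Fasl, the death receptor ligand, at 5.15 ± 0.24, Ccl5 at 4.53 ± 0.15, Xcl1 at 2.94 ± 0.16 and Ifng at 2.67 ± 0.17. Of 16 cytotoxic granule genes 10 were higher and 1 lower (1.1e-05; adjusted p = 0.0643 with an estimated correlation), with Gzma at 5.06 ± 0.40 and Gzmb at 4.62 ± 0.59. Of 29 naive and quiescence genes 11 were lower and none higher (6.54e-07; adjusted p = 0.0643 with an estimated correlation), Itgae among them (-2.56 ± 0.17). Of 33 cell cycle genes 16 were higher and none lower (6.54e-07; adjusted p = 0.155 with an estimated correlation), including Aurkb (2.55 ± 0.29), Ccna2 (2.53 ± 0.32) and Mki67 (2.27 ± 0.25). Of 27 interferon-stimulated genes 9 were higher (2.02e-05; adjusted p = 0.347 with an estimated correlation), with Mx1 at 2.60 ± 0.55 and Oasl2 at 1.82 ± 0.45. Ribosome biogenesis genes were lower in 6 of 30 (6.74e-06; adjusted p = 0.329 with an estimated correlation), with Gnl3 at -0.80 ± 0.16. Sterol genes were lower in 4 of 19 (0.0019; adjusted p = 0.155 with an estimated correlation), with Sqle at -0.77 ± 0.12. In the fit with the receptor factor Mx1 (2.82, adjusted p = 0.148), Oasl2 (2.27, adjusted p = 0.15), Gnl3 (-0.82, adjusted p = 0.128) and the sterol list (0.615) did not pass.

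Chromatin-modifying enzymes were lower in 7 and higher in 1 of 45 (camera adjusted p = 0.00349; adjusted p = 0.155 with an estimated correlation). Heat shock and stress genes were lower in 5 and higher in 1 of 16 (0.0164; adjusted p = 0.37 with an estimated correlation), with Hspa5 at -0.67 ± 0.15. NF-kappaB genes were lower in 5 and higher in 2 of 20 (0.0475, or 0.37 with that estimate). With quantile scaling of the processed signal none of these 3 lists passed (0.0768, 0.108 and 0.295). The receptor factor left chromatin-modifying enzymes at 0.912, NF-kappaB genes at 0.0823 and Hspa5 at -0.52 (adjusted p = 0.311). The NF-kappaB list did not pass without memory resting replicate 1, 2 or 3, naive resting replicate 2 or 4, naive stimulated replicate 1 or memory stimulated replicate 1 (0.0509 to 0.0946), and the heat shock list without memory resting replicate 2 (0.0519). Activation-induced receptors (6 higher and 4 lower of 21, adjusted p = 0.21), apoptosis regulators (2 and 3 of 22, 0.191) and glycolysis (0 and 3 of 22, 0.548, with a median of 0.14, a mean of 0.05 and a test pointing down) did not pass. Adjusted over the list alone, 2 immediate early genes were higher and 17 lower, 2 cytotoxic and 2 memory genes lower, 3 NF-kappaB genes higher and 6 lower, and 13 interferon-stimulated genes higher, with the same counts elsewhere.

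Markers of other cell types were higher in resting memory cells. Of 11 NK or NKT markers 10 were higher, with a median of 3.53 (camera adjusted p = 1.31e-13; adjusted p = 0.00426 with an estimated correlation), and memory CD8 T cells are known to carry many of these receptors themselves. Ncr1, an NK cell receptor gene, was above background on 1 of 4 memory and no naive arrays and did not pass (adjusted p = 0.0829), but did without naive resting replicate 4 (0.0207) or memory stimulated replicate 4 (0.0157). Of 9 dendritic cell and MHC class II markers 7 were higher (9.37e-06; adjusted p = 0.0165 with an estimated correlation). H2-Aa was at 1.98 ± 0.33, H2-Ab1 at 1.71 ± 0.22, H2-Eb1 at 1.60 ± 0.16 and Itgax at 2.50 ± 0.51, while Cd74, the invariant chain, at 0.40 ± 0.58 (adjusted p = 0.672). Of 5 CD4 or regulatory T cell markers 3 were higher (0.000162; adjusted p = 0.0161 with an estimated correlation), with Cxcr5 at 4.02 ± 0.17 and Zbtb7b at 3.44 ± 0.25, the latter above background on 1 of 4 naive arrays. Cd4 itself differed by 0.29 ± 0.17 (adjusted p = 0.26), and by 0.51 without naive resting replicate 1 (adjusted p = 0.00279). Of 14 monocyte, macrophage or neutrophil markers 7 were higher (0.00711; adjusted p = 0.109 with an estimated correlation), such as Ly86 (1.86 ± 0.20) and Lyz2 (1.52 ± 0.30, with a second probe at 0.66, adjusted p = 0.321). The neutrophil genes S100a9 (0.25 ± 0.42, adjusted p = 0.729) and Camp (0.37 ± 0.68, adjusted p = 0.749) did not pass. In the B cell list 1 of 7 was higher, Cd22 (1.64 ± 0.31, 1 of 4 naive arrays above background; list 0.212). T cell markers were higher in 0 and lower in 1 of 11 (0.363, with a median of 0). Of 4 erythrocyte or platelet markers the haemoglobin gene Hba-a1 was higher (0.78 ± 0.17; list 0.561), and its second probe was at 0.06 (adjusted p = 0.91). Itgax (1.79, adjusted p = 0.298), Lyz2 (1.96, adjusted p = 0.0645), Cd22 (2.01, adjusted p = 0.0728) and Hba-a1 (0.16, adjusted p = 0.772) did not pass with the receptor factor. The only gamma-delta T cell marker tested, Il23r, was not well above background on any resting array. Adjusted over the list alone, 11 NK or NKT and 4 CD4 or regulatory T cell markers were higher, and the other marker counts were the same.

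The split of calls at rest depended on how dim probes were scaled. Of the called genes 65% were higher in memory cells, against 50.9% (2116 higher and 2038 lower) with normexp and quantile scaling, 50.2% (2224 and 2203) with the authors' table, 48.3% (1696 and 1817) with the repaired normexp and 51.0% (2112 and 2027) with that and quantile scaling. The split turned to 43.1% (2282 and 3007) with a correction for probe GC content and to 34% (466 and 904) among genes with a mean level of at least 0, and was 52.9% (540 and 480) with the receptor factor. With the replicate number as a block 2410 genes were lower. Fewer genes were lower without memory resting replicate 1 (851), naive resting replicate 2 (886) or naive resting replicate 3 (901), and without naive resting replicates 1 and 4, which stood apart from the rest of their group, 3258 were higher and 1436 lower.

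The fourth comparison sets memory against naive cells after stimulation. Stimulated memory cells had more transcript of Ccl1 and Il17a, of several other cytokines and of the same lectin-like receptors. Ccl1 (chromosome 11, 82258409 to 82258468) was higher by 6.67 ± 0.42 (adjusted p = 3.5e-08; 1 of 4 naive stimulated arrays above background), Klra7 by 6.45 ± 0.37, Klra23 by 5.99 ± 0.31 and Il17a by 5.77 ± 0.61 (2 of 4 naive arrays). Gcnt1, a glycosyltransferase gene, was higher by 5.72 ± 0.41 (1 of 4), Klrc3 by 5.32 ± 0.35 and Il18rap by 5.32 ± 0.25 (2 of 4). Others were the calcium-binding S100a6 (5.14 ± 0.17) and Tmem163, at least 15.4-fold higher. Higher genes numbered 1814 and lower genes 2619, of which 716 and 1048 changed at least 2-fold.

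The 10 genes lowest in stimulated memory against naive cells were Pgk2, Tbc1d19, Rtbdn, Bmp3, Angptl7, Plaat5, Tenm4, Bcl2l14, Arhgap32 and Tmem100. The probes of 9 of them, all but Plaat5, hold at least 7 bases in a row of the C-rich strand of the telomeric repeat. Pgk2 was at least 48.3-fold, Rtbdn at least 34.8-fold, Bmp3 at least 18.2-fold and Tmem100 at least 7.18-fold lower in memory cells. The others ran from -5.70 ± 0.89 (Tbc1d19, 3 of 4 memory arrays above background) over Angptl7 (-5.22 ± 0.89), Plaat5 (-5.04 ± 0.94, 3 of 4), Tenm4 (-4.85 ± 0.93, 2 of 4) and Bcl2l14 (-4.77 ± 0.88) to Arhgap32 (-4.71 ± 0.83), with adjusted p up to 0.00665 among all 10. None of the 10 passed with the receptor factor (adjusted p 0.335 for Pgk2 to 0.998 for Plaat5), under which Pgk2 was at -4.45, Tbc1d19 at -1.58 and Plaat5 at -0.01, and Bmp3 (0.23), Tenm4 (0.09) and Tmem100 (2.37) turned positive. Their spread within groups was wide, with an SD of 2.50 for Pgk2 in naive resting cells. Over 115 probes with 8 or more such bases the mean level was 0.91 ± 0.44 (SD, n = 4) in naive stimulated and -0.95 ± 0.13 in memory stimulated cells, against -0.13 ± 0.74 and 0.10 ± 0.77 in naive and memory cells at rest. Over 60 probes with the G-rich strand it was -0.99 ± 0.03 and -1.06 ± 0.07 after stimulation.

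**Figure D3:**
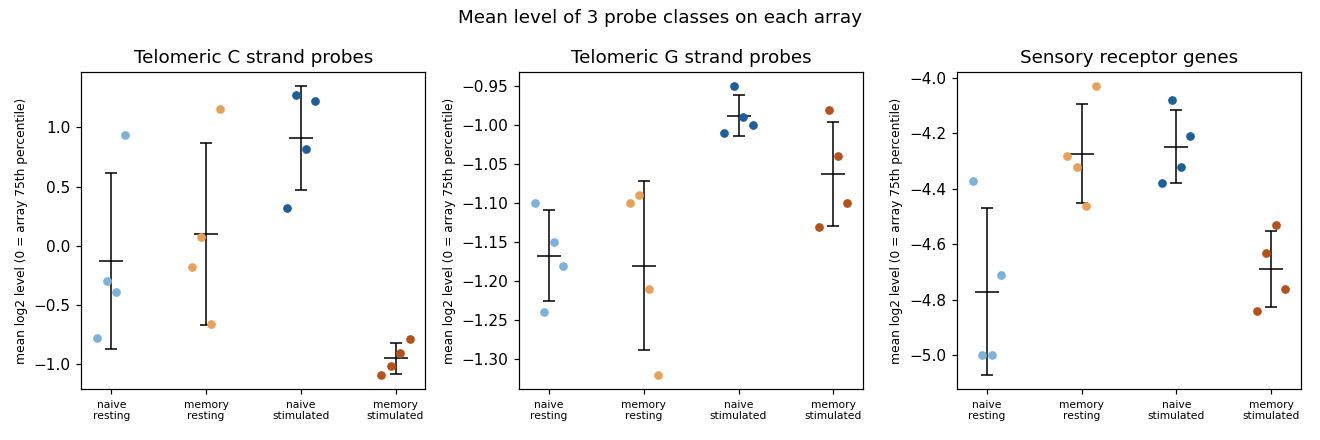
Mean level per array (points; log2 signal relative to the array's 75th percentile) of probes that hold the C-rich or the G-rich strand of the telomeric repeat and of sensory receptor genes, with the mean and SD of each group of 4 arrays. The C-strand probes were at 0.91 in naive stimulated and -0.95 in memory stimulated cells, while the G-strand probes were at -0.99 and -1.06.

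Of 31 memory and effector genes 26 were higher and 2 lower in stimulated memory cells (camera adjusted p = 3.32e-22; adjusted p = 0.000401 with an estimated correlation). Those lower were Tbx21 (-1.91 ± 0.20, adjusted p = 6.91e-06) and Itga4 (-1.24 ± 0.35, adjusted p = 0.017), and Itga4 did not pass without memory stimulated replicate 3 (-1.02, adjusted p = 0.0561). Tbx21 did not pass with the receptor factor (-1.08, adjusted p = 0.162). Of 30 cytokines and chemokines 19 were higher and 3 lower (camera adjusted p = 4.87e-15; adjusted p = 0.0147 with an estimated correlation). Il3 was higher by 5.07 ± 0.55, Csf2 by 4.80 ± 0.43, Ccl5 by 3.55 ± 0.15, Ifng by 1.98 ± 0.17 and Il2 by 1.93 ± 0.21. Il21 was at least 7.35-fold higher, and Cxcl10 (-1.91 ± 0.40) and Ltb (-1.33 ± 0.15) were lower. Under the receptor factor Cxcl10 (-1.67, adjusted p = 0.354) and Ltb (-1.24, adjusted p = 0.0678) did not pass. Of 16 cytotoxic granule genes 10 were higher and none lower (camera adjusted p = 6.42e-08; adjusted p = 0.0208 with an estimated correlation), with Gzma at 4.76 ± 0.40, Gzmb at 2.72 ± 0.59 (1.44 with the receptor factor, adjusted p = 0.599) and Gzmk at least 3.36-fold. Of 33 cell cycle genes 16 were higher (3.16e-09; adjusted p = 0.13 with an estimated correlation), including Ccna2 (2.45 ± 0.32) and Aurkb (2.43 ± 0.29, 1 of 4 naive arrays above background). Neither this list (0.226) nor Ccna2 (1.88, adjusted p = 0.182) or Aurkb (2.17, adjusted p = 0.0972) passed with the receptor factor. Of 29 naive and quiescence genes 9 were lower and 2 higher (0.00336; adjusted p = 0.285 with an estimated correlation), with Ccr9 at -3.56 ± 0.21 and Itgae at -2.03 ± 0.17. Of 19 sterol genes 7 were lower (0.00878; adjusted p = 0.285 with an estimated correlation), with Sqle at -0.72 ± 0.12 (-0.60 with the receptor factor, adjusted p = 0.25).

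No ribosome biogenesis gene of 30 passed in either direction in this comparison (limma; list adjusted p = 0.597), whereas 6 of them were lower at rest. Other lists that did not pass were activation-induced receptors (7 higher and 4 lower of 21, 0.102, 0.0363 without naive stimulated replicate 1 and 0.0263 with the receptor factor), interferon-stimulated genes (5 and 3 of 27, 0.38) and chromatin-modifying enzymes (2 and 4 of 45, 0.636, and 0.0093 with the receptor factor). The same held for glycolysis (2 and 2 of 22, 0.7), apoptosis regulators (1 and 3 of 22, 0.73), immediate early factors (1 and 4 of 21, 0.795), NF-kappaB genes (0 and 3 of 20, 0.986) and heat shock genes (1 and 1 of 16, 0.986). For the last 2 lists the medians of -0.02 and -0.07 and the means were negative while the test pointed up. Adjusted over the list alone, 21 cytokines were higher and 4 lower, 12 naive and quiescence genes, 6 receptors and 9 sterol genes lower, 1 glycolysis gene higher and 0 heat shock genes lower, and the others were the same. NK or NKT markers were higher in 11 of 11 (camera adjusted p = 3.01e-13; adjusted p = 0.00476 with an estimated correlation). CD4 or regulatory T cell markers were higher in 2 of 5 (0.0189; adjusted p = 0.111 with an estimated correlation) and monocyte, macrophage or neutrophil markers in 5 of 14 (0.0241; adjusted p = 0.201 with an estimated correlation), with Clec7a at 3.24 ± 0.31 and Fcgr3 at least 2.38-fold. Dendritic cell and MHC class II markers were higher in 2 and lower in 1 of 9 (0.0241; adjusted p = 0.201 with an estimated correlation), with Batf3 at 1.29 ± 0.23, H2-Eb1 at 0.79 ± 0.16 and Cd74 at -2.01 ± 0.58. Cd74 did not pass without naive stimulated replicate 2 (-1.89, adjusted p = 0.0548) or 4 (-1.83, adjusted p = 0.0591). Cd74 (-0.77, adjusted p = 0.793), H2-Eb1 (0.76, adjusted p = 0.28), Fcgr3 (0.459) and Clec7a (2.78, adjusted p = 0.0542) did not pass with the receptor factor. T cell markers showed 4 higher and 1 lower of 11 (0.0693), with Thy1 at 0.78 ± 0.22 (adjusted p = 0.0187), which did not pass without naive stimulated replicate 2 (0.0643), naive stimulated replicate 3 (0.0656) or memory stimulated replicate 3 (0.0501), or with the receptor factor (0.0693). B cell markers showed 0 and 1 of 7 (0.9) and erythrocyte or platelet markers 0 and 1 of 4 (0.435), and the gamma-delta marker Il23r was at least 2.2-fold higher, on 3 of 4 memory arrays above background, and did not pass with the receptor factor (0.0559). With markers adjusted over the list alone, 4 dendritic cell or MHC class II markers were higher.

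Of the genes called in this comparison 40.9% were higher in memory cells, against 51.2% (2012 higher and 1917 lower) with normexp and quantile scaling, 49.4% (1600 and 1640) with the repaired normexp and 51.0% (2017 and 1935) with that and quantile scaling. The split turned to 60.4% (3151 and 2063) with a correction for probe GC content, 75.6% (811 and 262) with the receptor factor and 53.6% (713 and 617) among genes with a mean level of at least 0. The differences at rest and after stimulation shared no array and 692 higher genes (251 for independent lists) and 309 lower genes (196), or 126 and 9 with the receptor factor. A further 699 genes were higher at rest and lower after stimulation, and 59 the reverse. Across genes the 2 differences correlated at r = 0.2 (rho 0.038, covariance 0.098), and at 0.338 over the 7580 genes with a mean level of at least 0.

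The last comparison asks which genes answered stimulation differently in the 2 cell types, as the interaction (memory response minus naive response). Single cytokine genes such as Il21 had the stronger rise in memory cells, while the cytokine list as a whole did not pass, and Tbx21, which encodes T-bet, rose in naive cells only. Il21 (chromosome 3, 37033994 to 37034053) was at -2.72 ± 0.08 in stimulated memory cells and not well above background in the other 3 groups (interaction adjusted p = 4.65e-12). Tbx21 (chromosome 11, 97207142 to 97207201) went from -0.36 ± 0.44 to 5.76 ± 0.33 in naive cells and from 3.69 ± 0.11 to 3.85 ± 0.15 in memory cells, an interaction of -5.96 ± 0.28 (adjusted p = 2.06e-09). The interaction was higher for 1033 genes and lower for 2600, of which 339 and 1983 by at least 2-fold.

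The highest interactions were in Ccl1 (6.54 ± 0.59), Il3 (5.82 ± 0.77), Il17a (5.73 ± 0.86), Il21, the carboxypeptidase gene Cpa4 (4.49 ± 0.33), Csf2 (4.03 ± 0.61), Il10 (3.90 ± 0.45), Il22 (3.81 ± 0.81), Negr1 (3.60 ± 0.55) and Il17f (3.45 ± 0.60), with adjusted p up to 0.00383. For all of these except Il10 and Il17f at least 1 group was not well above background on any array, so that the size of the interaction is not settled. Other genes with the smaller response in memory cells were Rel (-3.13 ± 0.37), Cxcr3 (-2.85 ± 0.33), Irf8 (-2.69 ± 0.27) and the interferon regulatory factor gene Irf1 (-2.44 ± 0.28). Others were Cxcl10 (-2.27 ± 0.57), Fasl (-1.89 ± 0.35), Ccl4 (-1.40 ± 0.23), Xcl1 (-1.33 ± 0.23) and Ccl3 (-1.20 ± 0.20). Cd44 was at -1.47 ± 0.27 (adjusted p = 0.00156), and at 1.41 by its near-background probe (adjusted p = 0.0212). Fasl and Xcl1 did not pass with normexp and quantile scaling (-0.46, adjusted p = 0.144, and -0.39, adjusted p = 0.214). With the receptor factor Rel (-0.24, adjusted p = 0.897), Cxcr3 (-1.10, adjusted p = 0.513), Irf1 (-2.38, adjusted p = 0.146), Cxcl10 (-1.86, adjusted p = 0.597) and Fasl (-3.30, adjusted p = 0.0933) did not pass. Nor did Ccl4 (-1.17, adjusted p = 0.365), Xcl1 (-0.27, adjusted p = 0.854), Ccl3 (-1.58, adjusted p = 0.157), Cd44 (-2.19, adjusted p = 0.161), Il17a (7.92, adjusted p = 0.121), Csf2 (5.17, adjusted p = 0.148), Il10 (5.32, adjusted p = 0.0589), Il22 (1.61, adjusted p = 0.759) or Il17f (3.77, adjusted p = 0.277). For Il2, not well above background on any naive resting array, the interaction is not settled. Ifng (-0.69 ± 0.24, adjusted p = 0.061) did not pass, but did without naive resting replicate 1 (0.0148) or naive stimulated replicate 4 (0.0309).

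The lowest interactions by rank were in Pgk2 (-9.82 ± 1.51), Tbc1d19, Rtbdn, Bmp3, Vmn1r237, Sft2d1, Tenm4, Plaat5, Angptl7 and Cep20 (-6.19 ± 0.64), with adjusted p up to 0.0026, and the probes of 6 of these 10 hold at least 7 bases of the telomeric C-rich strand. In Pgk2, Rtbdn, Bmp3, Sft2d1 and Cep20 at least 1 group was not well above background on any array. Of the 10 only Sft2d1 passed with the receptor factor. Under it Pgk2 was at -5.66 (adjusted p = 0.52), Tbc1d19 at -0.38 (0.965), Rtbdn at -0.79 (0.932), Angptl7 at -2.10 (0.8) and Cep20 at -4.20 (0.24), while Bmp3 (2.19), Vmn1r237 (1.55), Tenm4 (1.67) and Plaat5 (1.86) turned positive. Of the called genes with a mean level under -4, 85.5% had the lower interaction, and of those at 0 and above, 39.7%. The share of calls that were higher, 28.4%, was 40.6% (1321 higher and 1931 lower) with quantile scaling of the processed signal, 45.9% (1679 and 1976) with the authors' table, 47.9% (1618 and 1763) with normexp and quantile scaling, 46.2% (1208 and 1409) with the repaired normexp and 47.4% (1601 and 1777) with that and quantile scaling. The split turned to 62.3% (3667 and 2215) with a correction for probe GC content, 64.5% (182 and 100) with the receptor factor and 60.8% (589 and 380) among genes with a mean level of at least 0, so that its direction is not settled.

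Of 21 immediate early and activation transcription factors 14 had the larger response in memory cells and 2 the smaller, with a median interaction of 1.14 (camera adjusted p = 4.91e-07; adjusted p = 0.147 with an estimated correlation). Fos was at 2.44 ± 0.27, Egr2 at 2.21 ± 0.25, Nr4a1 at 1.94 ± 0.18 and Myc at 1.30 ± 0.16, and all 4 were lower in memory cells at rest. The interactions of Egr2 (2.84, adjusted p = 0.0681) and Myc (1.12, adjusted p = 0.217) did not pass with the receptor factor. After stimulation none of the 4 passed between memory and naive cells (Fos -0.12, adjusted p = 0.678; Egr2 0.41, 0.106; Nr4a1 -0.05, 0.791; Myc -0.07, 0.703). Egr2 did without memory stimulated replicate 1 (0.57, adjusted p = 0.0235). Of 30 ribosome biogenesis genes 5 were higher, with a median of 0.35 (camera adjusted p = 0.000229; adjusted p = 0.755 with an estimated correlation), for example Gnl3 (0.92 ± 0.22) and Ppan (0.90 ± 0.26, adjusted p = 0.0255), of which Ppan did not pass without memory resting replicate 1 (0.75, adjusted p = 0.05) or memory stimulated replicate 3 (0.80, adjusted p = 0.0531). The ribosome biogenesis list (median 0.60, adjusted p = 0.276), Gnl3 (0.96, 0.452) and Ppan (1.73, 0.232) did not pass with the receptor factor. The other lists did not pass. They were interferon-stimulated genes (0 higher and 4 lower of 27, 0.0767, and 0.0126 with the receptor factor), cytokines (10 and 8 of 30, 0.129) and heat shock genes (0 and 0 of 16, 0.129). Next came memory and effector genes (5 and 10 of 31, 0.237), chromatin-modifying enzymes (4 and 3 of 45, 0.237), NF-kappaB genes (4 and 2 of 20, 0.264, with Nfkbid at 1.61 ± 0.36 and at 2.22 with the receptor factor, adjusted p = 0.273) and naive and quiescence genes (4 and 3 of 29, 0.291). The rest were cytotoxic granule genes (1 and 1 of 16, 0.405), glycolysis (1 and 0 of 22, 0.535), activation-induced receptors (3 and 2 of 21, 0.535, with Cd160 at 1.55 ± 0.37 and at 3.93 with the receptor factor, adjusted p = 0.0506), cell cycle (1 and 0 of 33, 0.622, and 0.0235 with the receptor factor), apoptosis regulators (2 and 1 of 22, 0.672) and sterol genes (0 and 0 of 19, 0.874).

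The interferon-stimulated list passed, downward, without memory stimulated replicate 1 (0.000936), memory resting replicate 2 (0.0272) or memory resting replicate 4 (0.00635) and with quantile scaling (0.0102), and the memory and effector list passed with quantile scaling (0.0149). The cytokine list passed upward without memory resting replicate 1 (0.0382) and with normexp and quantile scaling (0.0059), and downward among genes above background on all 16 arrays (a median of -0.70, 0.00966). Adjusted over the list alone, 12 cytokines were higher and 9 lower, 11 memory genes lower, 5 NF-kappaB and 4 ribosome biogenesis genes higher, 4 receptors lower, 3 chromatin-modifying enzymes higher, and 0 cell cycle genes and 0 apoptosis regulators higher, with the same counts elsewhere. Median, mean and test differed in sign for glycolysis (-0.07, 0 and up), cytotoxic granule genes (0.24, -0.10 and up), activation-induced receptors (-0.05, 0.01 and up), cell cycle (0.01, -0.01 and up) and sterol genes (-0.04, -0.08 and up). Among markers the interaction was lower in 4 of 9 dendritic cell and MHC class II genes (0.0672), with H2-Ab1 at -1.21 ± 0.31 (-1.80 with the receptor factor, adjusted p = 0.303), in 2 of 5 CD4 or regulatory T cell genes (0.0774), and in 1 of 7 B cell genes (0.285). It was lower in 4 and higher in 1 of 11 NK or NKT genes (0.285), lower in 1 of 4 erythrocyte or platelet genes (0.434), and higher in 3 of 11 T cell genes (0.0774) and in 1 of 14 monocyte, macrophage or neutrophil genes (0.941). Adjusted over the list alone 5 dendritic cell or MHC class II, 2 B cell, 5 NK or NKT and 1 T cell marker were lower.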

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

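The tests of background handling, of the sensory receptor genes, of the CD8 share and of dendritic cells or macrophages were chosen only after the result was seen. The tests on GC content and on the other probes of the repeat-bearing genes, and the splits of the arrays, were written before their result.

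The first pattern is that 2600 of the interaction calls were lower and 1033 higher, and that the lower ones were mostly at low signal. GC content of the probe stays open: after the GC correction the 411 sensory receptor genes, which T cells are not known to use, kept a median interaction of -0.77, but the split of all calls turned to 3667 higher and 2215 lower, while the median of all genes moved to 0.22, so the bound written beforehand for the receptor genes did not cover the pattern. Background handling of dim probes could account for much of the split: with the repaired normexp at the same scaling 53.8% of the calls were lower. A slide-level difference in hybridisation stays open, since each slide held 1 group. The median interaction of the receptor genes was -1, with 191 lower and 28 higher. The filter kept receptor genes bright in any group, which may build in part of this. A biological difference between the cells in how many transcripts they gain or lose was not tested and stays open.

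The second pattern is that 115 probes with 8 or more bases of the C-rich strand of the telomeric repeat had a median difference of -1.79 between memory and naive cells after stimulation. The tables argue against GC content of the probe, since the median was -1.65 after the GC correction. Cross-hybridisation to telomeric repeat sequence could account for it: the 85 other probes of 49 of the same genes had a median difference of -0.17, against -1.2 for the repeat probes of those genes. The 60 probes with the G-rich strand had a median difference of -0.07. Whether the signal comes from telomeric transcripts, from DNA carried over or from the slide was not tested, and a biological difference between the cells stays open.

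The third pattern is that markers of other cell types were higher in resting memory than in resting naive cells. A lower share of CD8 T cells with all other types alike stays open. The mean difference of 3 MHC class II genes exceeded that of 4 neutrophil genes by 1.55 (95% interval 0.04 to 3.06). The test was chosen after the result and left out Cd74. An earlier bound failed: the lowest of the 3 (1.6) and the highest neutrophil gene (0.37) were 1.76 SE apart, not over 2. Dendritic cells or macrophages cannot be told apart from expression by the memory cells, since the interval for Cd74 reached 1.63. The sort gate on CD8 and Thy1.2 was set to remove such cells, and expression of these genes by memory cells themselves was not tested.

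Of 35 ways to split the 8 arrays of a comparison only the real one (1) gave as many genes. Other splits mix the groups, which widens the spread, so chance is not excluded. The real and the highest other count were 6761 and 3 (higher) and 5895 and 3 (lower) in the naive response, and 5533 and 1, and 7505 and 1, in the memory response. For memory against naive cells they were 2548 and 5, and 1375 and 5, at rest, and 1814 and 292, and 2619 and 292, after stimulation. For the interaction, of 100 splits drawn, the real one (1) gave as many, with 1033 against 332 higher and 2600 against 175 lower. A split by array leaves slide and group joined and so says nothing on the slides.

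In 560 sets of 4 replicates of a named gene, 46 (8.21%) had 1 array whose gap to its nearest neighbour, as a share of the range, was over Dixon's 95% critical value, against about 5% by chance. In naive resting replicate 1 the levels of Aurkb (-3.90), Ccr9 (1.86), Cd4 (-3.80), Itgae (3.68), Lrrc75b (-0.62), Pik3ip1 (4.76) and Tnfsf14 (-1.66) were above, and of Idi1 (0.54) below, the other 3 arrays. In naive resting replicate 2 Csf2 (-7.33), Klre1 (-6.68) and Pdgfrb (-1.20) were above, and in replicate 3 Cpa4 (-5.77) was below. In naive resting replicate 4 Plaat5 (-1.85), Rtbdn (-1.12), Tbc1d19 (0.41) and Tenm4 (-1.35) were above, and the probes of the last 3 hold the telomeric repeat. In memory resting replicate 1 Cd22 (-4.22), Ifit2 (0.32), Oasl2 (2.44) and Tsc22d3 (4.30) were above and Ngp (-2.34) and S100a9 (2.11) below. In memory resting replicate 4 Ccl1 (-6.73), Cpa4 (-6.88), Il3 (-6.56) and Sft2d1 (-2.22) were above and Ccl4 (2.01) below.

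Among stimulated naive arrays, replicate 1 was above the others in Hk2 (5.91) and P2rx5 (-4.95) and below in Egr2 (6.62) and Tcf7l2 (-2.62). Replicate 4 of that group was above in Gzmk (-6.87), H2-Aa (-3.79) and Plaur (3.77) and below in Cd160 (-0.33) and Ifng (6.12). Among stimulated memory arrays, replicate 1 was above in Mx1 (-3.10) and P2rx5 (-5.48) and below in Egr2 (7.02) and Zcchc12 (-3.37). Replicate 2 was below in H2-Eb1 (-1.41) and replicate 3 in Itga4 (-1.69). Replicate 4 was above in Klra23 (3.29), Klra4 (0.01), Klra7 (3.78) and Pik3ip1 (-1.51).

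The response differed between memory and naive cells by the interaction test in 53 named genes. It was larger or less negative in memory cells in Ccl1 (6.54), Il3 (5.82), Il17a (5.73), Il21 (5.11), Cpa4 (4.49), Csf2 (4.03), Il10 (3.90), Il22 (3.81), Negr1 (3.60), Il17f (3.45), Gprc5b (2.84), Il18r1 (2.65), Fos (2.44), Slc6a19 (2.29), Egr2 (2.21), Nr4a1 (1.94), Nfkbid (1.61), Cd160 (1.55), Fosl1 (1.40), Myc (1.30), Fam78a (1.01), Gnl3 (0.92), Ppan (0.90) and Siae (0.86). It was smaller or more negative in Pgk2 (-9.82), Tbc1d19 (-7.43), Rtbdn (-7.35), Bmp3 (-7.18), Vmn1r237 (-7.04), Sft2d1 (-6.78), Tenm4 (-6.76), Plaat5 (-6.73), Angptl7 (-6.31), Cep20 (-6.19) and Tbx21 (-5.96). The same held for Rel (-3.13), Gzmk (-2.94), Cxcr3 (-2.85), Irf8 (-2.69), Irf1 (-2.44), Cxcl10 (-2.27), Fasl (-1.89), Lag3 (-1.87), Cd44 (-1.47), Kcnj8 (-1.45), Ccl4 (-1.40), Xcl1 (-1.33), H2-Ab1 (-1.21), Ccl3 (-1.20), Ltb (-1.10), Zeb2 (-1.04), Pik3ip1 (-0.91) and Tnfsf14 (-0.86). For Ccl1, Il3, Il17a, Il21, Cpa4, Csf2, Il22, Negr1, Gprc5b, Slc6a19, Siae, Pgk2, Rtbdn, Bmp3, Sft2d1, Cep20, Gzmk, Lag3 and Kcnj8 at least 1 group was not well above background on any array, so that the size of the interaction is not settled. It also differed for the immediate early factors (a median of 1.14) and the ribosome biogenesis genes (0.35, with 5 of 30 genes past the test), but with an estimated correlation neither list passed (adjusted p = 0.147 and 0.755).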

How the results depend on the processing

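Settings added after the values were seen, such as the repaired normexp and the receptor factor, are named above. Over all settings, including those that leave out an array, 8767 named-gene results kept their side of the threshold. Another 180 no longer passed, 32 newly passed and 11 reversed. For gene lists these were 2324, 87, 56 and 8. Of the 180, the planned normexp with the 75th percentile, whose fit failed on 3 arrays, ended 71. The receptor factor, which largely follows the groups, ended 60. Of the 87, the estimated correlation ended 30, most of the list calls. Signal over background limits the sizes of folds of dim genes. Blocks by slide or by scan date were not run, because each slide holds 1 group.

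With the failed normexp and the 75th percentile, 3829 genes rose and 2956 fell in naive cells and 3124 fell in memory cells. The memory against naive counts were 442 higher and 117 lower at rest, 286 and 206 after stimulation, and 37 and 191 in the interaction. The overlaps were 3070 higher and 2447 lower between responses and 150 and 24 between cell type differences. Medians reversed after stimulation for immediate early factors (-0.214), ribosome biogenesis genes (-0.333) and glycolysis (-0.082), and in the interaction for ribosome biogenesis (-0.014) and cell cycle genes (-0.22). Il23r reversed at rest (-0.033). The failed fit on 3 arrays is part of this setting's construction. With the repaired version, 1696 genes were higher at rest, 1640 lower after stimulation and 1409 lower in the interaction, the correlation of the responses was 0.89 and Il23r was at -0.033. With the repaired version and quantile scaling, 1601 were higher in the interaction and the correlation was 0.889.

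With normexp and quantile scaling the interaction had 1618 higher genes and the correlation was 0.895. The authors' table gave 2203 lower genes at rest, 1679 higher in the interaction and a correlation of 0.874. Among genes above background on all 16 arrays, 1652 were lower in the interaction, the correlation was 0.875 and the cytokine median -0.696. With a mean level of at least 0, fewer genes were tested: 3388 rose and 2540 fell in naive cells, 3592 and 2417 in memory cells, 466 were higher and 904 lower at rest, 713 and 617 after stimulation, and 589 and 380 in the interaction. The correlation was then 0.934, the overlaps 3068 and 2120 between responses and 169 and 136 between cell type differences, and the cytokine median -0.985. With each probe on its own, more probes were tested: 10245 rose in naive and 8750 in memory cells, 7454 in both, and Cd44 reversed in the interaction (1.405).

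At an adjusted p under 0.05 and at least 2-fold, 3899 rose and 3696 fell in naive cells, 3322 and 4730 in memory cells, 1299 were higher and 235 lower at rest, 716 and 1048 after stimulation and 339 higher in the interaction. The overlaps were 2664 higher and 3081 lower, and 410 and 78. At an adjusted p under 0.01, 1584 and 558 were called at rest, 1033 and 1435 after stimulation and 362 and 1587 in the interaction, with overlaps of 454 and 126. The GC correction gave 3007 lower at rest, 3151 higher after stimulation and 3667 higher in the interaction. With the receptor factor 3422 rose in naive cells and 3521 fell in memory cells, 540 and 480 were called at rest, 811 and 262 after stimulation and 182 and 100 in the interaction. Its correlation was 0.594 and its overlaps were 2303 and 2384, and 126 and 9. It reversed Bmp3 (0.23), Tenm4 (0.094) and Tmem100 (2.366) after stimulation, Itga4 at rest (0.465), and Bmp3 (2.185), Vmn1r237 (1.55), Tenm4 (1.671), Plaat5 (1.863) and the cell cycle genes (-0.165) in the interaction. Except where the construction of a setting is named, the cause was not tested.

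Pairing by replicate number missed a check written beforehand but stays open. Of 24 same-numbered pairs, 16 had a correlation of deviations above 0.1 (range -0.21 to 0.59). The median was 0.16 against -0.07 for other pairs, and 32 of 48 comparisons were best with their own. The 4 pairs of a naive and a memory resting array were all above 0.1 (0.302 to 0.585). The other 5 pairs of groups each had at least 1 array pair below. With the replicate block 2410 genes were lower at rest, 1697 higher in the interaction and 682 lower in both cell type differences. With a random replicate block (consensus correlation 0.203) these were 2104, 1597 and 519. With the replicate block Egr2 (adjusted p = 0.0154) and Cd8a (0.0479) newly passed after stimulation. Il2 (0.0434) and interferon-stimulated genes (0.0159) did in the interaction, and cytotoxic granule (0.0477) and glycolysis genes (0.0369) in the memory response. With the random block Egr2 (0.0398) and, in the interaction, Il2 (0.0295) and Ifng (0.0467) did. No label ties a number to a sort run, and number equals slide position, so run and position stay joined.

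Leaving out 1 array at a time gave 6263 to 6960 genes up and 5580 to 5936 down in naive cells and 5241 to 5646 and 7078 to 7696 in memory cells. Memory against naive cells gave 1877 to 3263 higher and 851 to 1926 lower at rest, 1369 to 2111 and 1853 to 2962 after stimulation, and 724 to 1273 and 2167 to 3048 in the interaction. The correlation of the responses was 0.811 to 0.827. Overlaps were 4451 to 4684 higher and 4830 to 5004 lower between responses, and 598 to 765 and 217 to 436 between cell type differences.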

Other observations

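The 411 tested receptor genes had a mean level of -4.77 ± 0.30 (SD of 4 arrays) in naive resting and -4.27 ± 0.18 in memory resting cells. They were at -4.25 ± 0.13 in naive stimulated and -4.69 ± 0.14 in memory stimulated cells. The probes with the G-rich strand of the telomeric repeat were at -1.17 ± 0.06 in naive and -1.18 ± 0.11 in memory cells at rest.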
